A study of Mus musculus with 50 samples.

How the data were processed

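Spleen RNA of mice in 12 groups was measured on 50 two-colour arrays against a common reference RNA, with 1 array per sample. Per the labels, the spleen RNA carried Cy5 and the Universal Mouse Reference RNA Cy3 on every array. The 0.5 h arrays list their channels in the other order but carry the same dyes on the same RNA, and their values ran the same way as those of the other arrays, so no sign was turned. The deposited values are log2 ratios of spleen over reference. According to the series text, the authors subtracted background, removed bad spots, filtered out spots with both signals under 100, took log2 ratios, applied lowess normalization within each array and kept genes measured on more than 70% of the arrays, with BRB ArrayTools and mAdb. The genome build behind the probe design is not given in the sources used here.

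The table held 36607 probes, of which 5857 had no values and 30750 had values on at least 35 of the 50 arrays, or 70%. A value on every array was present for 21565 probes. Medians of the deposited log2 ratios lay between -0.0178 and 0.0197 per array, median absolute deviations between 0.379 and 0.586, and between 0.52% and 10.18% of the measured probes were missing on an array. Intensities and background were not used here, so the signal over background behind each ratio is unknown, and low spots had been removed before the ratios were made. Because both channels pass through lowess, a change of most genes in one direction would be removed from the ratios.

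Probes were named from the platform annotation, with 26926 probes carrying 1 gene symbol, 203 several and 9478 none. Symbols were brought up to date through gene identifiers for 26774 probes and through accessions for 35, and 117 kept the platform's name. In all 28 symbols were renamed. The reference gene table belongs to assembly GRCm38.p6 and served for names alone. Probes with several symbols or none were left out of the gene comparisons. Of 15312 named genes with a measured probe 5197 had more than 1 probe. The probe with most values over all arrays stood for the gene, with ties going to the first listed, and for genes named by the rule given here the text adds the values of other probes where 1 of them differed by over 1 on the log2 scale or gave under 0.5 times the change.

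Groups were taken from the array titles. The titles of the C57BL/6 control CpG arrays were followed over a second label field that names untreated mice, and the Tnf level of each array is given as a check. Per the labels, each time point holds 4 independent experiments. Whether arrays of the untreated groups came from separate days is not stated, and p-values measure the spread between these arrays.

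Each array was centred on the median of its log2 ratios over the probes kept, and a probe was kept when present on over 70% of the arrays of the fit. Per-array values can differ in the third decimal with the probes used for centring. Differences were tested with limma (lmFit and eBayes) on group means, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 34 BALB/c arrays formed a fit of 15264 genes, the 16 C57BL/6 arrays a fit of 14951 genes, and all 50 arrays a fit of 15262 genes for the difference between strains, of which 15219 could be tested. Contrasts between successive times were also fitted and are not reported. The comparisons were CpG ODN at each time against untreated spleen, control ODN against untreated spleen, CpG against control ODN, CpG against untreated spleen in C57BL/6 control and TNF-KO mice, TNF-KO against control at each treatment, and the differences of responses between genotypes and between strains.

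The 31 gene lists, 19 of pathways and 12 of cell types and neighbouring tissues, were tested with cameraPR on the moderated statistics with a preset correlation of 0.01 and again with a correlation estimated per list, and adjusted over the lists of a comparison. A count adjusted over the list alone applies Benjamini-Hochberg to the members of that list. Of 166 list calls over all comparisons 73 kept their call with an estimated correlation. Induced and repressed genes were those changed by at least 2-fold at 3 h in BALB/c. Their means per C57BL/6 array were compared by an exact two-sided permutation test of the genotype labels within each treatment, over 4900 arrangements. The overlap of calls was set against the number that independent lists would share, for pairs of comparisons with no array in common.

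Named genes follow a rule. Per comparison it takes the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05 for which every array of the first group lies on the same side of the other group's mean, by adjusted p alone for differences of responses, without provisional gene names. It adds up to 4 members of each list with the smallest p, and Tnf in every C57BL/6 array. Not every such gene is printed. Differences between the mixtures are also given for genes that the rule named after control ODN. The values of Tnf in the TNF-KO response and of 5 genes after control ODN lie outside the rule and were chosen after they were seen. The groups, tests, lists, this rule and the alternative settings, except those named as added later, were set before the data were examined.

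The alternatives were no centring, scaling of each array to the same spread, no filter on missing values, complete probes only, all probes, only the groups compared, array weights, a minimum of 2-fold, a replicate block, runs of adjacent array numbers as a block, the first run alone, each array left out in turn, an estimated correlation in the list tests, and other gene choices for the score. The mean of the pancreas list as a covariate and the overlaps of calls were added after seeing the data. Array numbers are only a proxy for batches. The first run held 5 untreated arrays, the 4 arrays of 0.5 h and 2 arrays of 1 h.

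The scripts for the gene tests were tested on simulated data with 200 changed genes. For the 3 h comparison in BALB/c 84 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were recovered, with 14 false calls. In C57BL/6 controls these numbers were 71, 100 and 8, and for the difference between strains 40, 92 and 7. The software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.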

Results

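Whole spleens of female mice were profiled on 50 two-colour long-oligonucleotide arrays after an intraperitoneal injection of oligodeoxynucleotides (ODN). The CpG mixture held phosphorothioate ODN with unmethylated CG dinucleotides, the ligands of Toll-like receptor 9 (TLR9), an endosomal receptor of B cells and dendritic cells. Each array measured the ratio of spleen RNA, labelled with Cy5, to a Universal Mouse Reference RNA, labelled with Cy3, which is a pool of RNA from several mouse cell types and tissues. BALB/c mice were untreated (n = 6 arrays) or received 400 µg of CpG ODN and were examined at 6 times, namely 0.5, 1 and 3 h and then 9, 24 and 72 h after injection (n = 4 arrays each), and a further group received control ODN and was examined after 3 h (n = 4). C57BL/6 control mice and TNF-KO mice, which lack tumor necrosis factor (TNF), were untreated or examined 3 h after CpG ODN (n = 4 arrays in each of the 4 groups). The C57BL/6 control arrays of the CpG group carry that treatment in their titles, by which they were grouped, while another label field of the same arrays names untreated mice. The labels give no dose for the C57BL/6 arrays.

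Of 36607 probes, 30750 had values, and the number of values per array lay between 27619 and 30590. The median correlation of an array with the others of its group lay between 0.85 and 0.928 across probes, and no pair of arrays held identical values. The number of arrays limits the precision of every comparison, and the median residual SD of a gene was 0.299 on the log2 scale in BALB/c and 0.305 in C57BL/6. Errors of log2 changes are standard errors from limma, and adjusted p-values are Benjamini-Hochberg values over all genes of a comparison. For the genes chosen by the size of their change between a pair of groups, every array of the first group lay on the same side of the mean of the other group.

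Transcripts of the pancreas, a neighbour of the spleen, were present at very different levels within every BALB/c group. The mean log2 ratio of 13 pancreas genes ran from 0.46 to 5.77 among untreated BALB/c arrays, from 0.30 to 5.30 at 24 h and from 0.96 to 6.78 after control ODN. In C57BL/6 it ran from 0.28 to 6.42 in untreated controls, from 3.41 to 6.67 in controls after CpG ODN, from 3.15 to 6.84 in untreated TNF-KO and from 5.70 to 6.61 in TNF-KO after CpG ODN. Cpb1, a pancreatic carboxypeptidase, ranged from 1.16 to 9.52 over the 40 arrays that measured it. Runs of adjacent array numbers in the titles, the only proxy for batches in the labels, also divided the arrays. The runs of the arrays of 9 h, 24 h, 72 h and control ODN held no untreated array, so run and group cannot be told apart when these groups are set against untreated spleen. The same holds for CpG against control ODN at 3 h, whose arrays shared no run. Of the BALB/c arrays 3 h after CpG ODN, replicates 1 and 2 lay in a run with no untreated array. Replicates 3 and 4 shared a run with untreated replicate 2 alone, so run and group are largely mixed at 3 h too.

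Within 0.5 h of CpG ODN the BALB/c spleen had raised mRNAs of neutrophil chemokines and immediate early transcription factors. Cxcl2, a chemokine that recruits neutrophils, rose by 4.18 ± 0.32 on the log2 scale (adjusted p = 9.1e-11) and Cxcl1 by 2.55 ± 0.29 (adjusted p = 1.1e-06). Fos, a subunit of the AP-1 transcription factor, rose by 3.79 ± 0.27 (adjusted p = 5.2e-11), and Nr4a1, an orphan nuclear receptor, by 2.74 ± 0.31 (adjusted p = 8e-07). Nfkbiz, an inducible regulator of NF-kB, rose by 2.66 ± 0.21 and Tnfaip3, a deubiquitinase that limits NF-kB signalling, by 1.76 ± 0.22 (adjusted p = 1.2e-10 and 4.6e-06). The cytokine genes Il1b and Tnf were higher by 2.72 ± 0.38 and 2.14 ± 0.36 (adjusted p = 4.2e-05 and 0.00083).

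In total 39 genes changed at 0.5 h, 38 upward and 1 downward, and 32 of them by at least 2-fold. The single fall, of Tas2r130, a bitter taste receptor gene, was -1.21 ± 0.27 (adjusted p = 0.048), and it did not pass with scaling to the same spread or with most arrays left out, reaching an adjusted p of 0.601 without replicate 1 of the 0.5 h arrays. Among 29 immediate early genes 12 rose, and 16 when adjusted over the list alone, with Dusp1 (2.55 ± 0.30) and Zfp36 (2.39 ± 0.22) beside Fos. The list moved upward against all other genes (adjusted p = 1.66e-26, and adjusted p = 1.2e-05 with an estimated correlation between genes). NF-kB pathway and feedback genes rose in 4 of 20 cases, 8 adjusted over the list alone, with a further 1 lower (adjusted p = 0.0294 with an estimated correlation). Of 30 chemokines 3 rose and of 26 inflammatory cytokines 2 rose, 6 and 7 adjusted over the list alone (adjusted p = 0.00293 and 0.0294 with an estimated correlation). No cell cycle gene of 32 changed, but the list had a median of -0.46 (adjusted p = 1.85e-09, and adjusted p = 0.386 with an estimated correlation). Its mean per array was -1.11, -1.56, 0.12 and 0.07 in replicates 1 to 4, so the low values lay in 2 of the 4 arrays. Array weights gave 85 genes in place of 39. Without replicate 1 of the 0.5 h arrays 21 genes passed, and without replicate 2 it was 22.

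At 1 h chemokine genes led the rises, with cytokine and feedback genes beside them. Cxcl2 stood 5.32 ± 0.32 above untreated spleen on the log2 scale, Cxcl1 5.21 ± 0.29 and Ccl4, a chemokine for monocytes and lymphocytes, 4.75 ± 0.25 (adjusted p = 3.7e-14, 1.9e-14 and 6.2e-15). Socs3, a feedback inhibitor of cytokine receptors, rose by 4.09 ± 0.24, and Il12b, which encodes a subunit of interleukin 12, by 3.57 ± 0.18 (adjusted p = 3.7e-14 for both). Il1a, Tnf and Ptgs2, the inducible cyclooxygenase, rose by 3.70 ± 0.38, 3.28 ± 0.36 and 2.24 ± 0.24, with another probe at 4.75 for Il1a and at 4.63 for Ptgs2. Cd14, a co-receptor for bacterial products, was higher by 3.65 ± 0.28, and Cd83, a marker of mature dendritic cells, by 3.72 ± 0.43 (adjusted p = 2.5e-07). The fewer falls included Zfp503, measured on 3 of the 1 h arrays (-1.61 ± 0.31, adjusted p = 0.0013), and Slc17a8, a glutamate transporter gene (-1.12 ± 0.20, adjusted p = 0.00047).

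At that time 503 genes passed, 459 higher and 44 lower. Immediate early genes rose in 17 of 29 cases and NF-kB pathway genes in 16 of 20, with 19 and 16 adjusted over the list alone (adjusted p = 5.01e-08 and 1.7e-07 with an estimated correlation). Chemokines rose in 12 of 30 cases and inflammatory cytokines in 11 of 26, each 14 adjusted over the list alone (adjusted p = 1.56e-09 and 1.02e-09 with an estimated correlation). Of 14 genes of dendritic cell maturation and co-stimulation 8 rose, 9 adjusted over the list alone, among them Cd274 (1.68 ± 0.22) and Cd83. Interferon-stimulated genes were higher in 10 of 44 cases, 22 adjusted over the list alone, such as Ifit1 (1.51 ± 0.25) and Mx2 (1.44 ± 0.23). Markers of neutrophils moved at the same time, 7 of 18 higher and all 18 adjusted over the list alone, with a median of 1.16 (adjusted p = 0.00836 with an estimated correlation). The neutrophil collagenase Mmp8 was higher by 2.93 ± 0.34 and Lcn2, an iron-sequestering protein of neutrophil granules, by 2.49 ± 0.37. Platelet genes were higher in 4 of 10 cases, 7 adjusted over the list alone (adjusted p = 0.0197 with an estimated correlation). The count of 503 became 299 with every array scaled to the same spread, 773 with all probes tested, 1001 with array weights, 264 with a minimum of 2-fold and 1690 in the first array run alone, which held 2 of the 1 h arrays and 5 untreated, and where Ifit1 (0.73) and Zfp503 (-1.23) did not pass (adjusted p = 0.0571 and 0.0879). Without replicate 2 of the 1 h arrays it was 287.

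At 3 h nearly all measured interferon-stimulated genes were raised. Ifit2 and Ifit3, antiviral RNA-binding proteins, rose by 4.57 ± 0.26 and 4.40 ± 0.30 on the log2 scale, and the double-stranded RNA sensors Ifih1 and Eif2ak2 by 3.43 ± 0.15 and 2.85 ± 0.17 (adjusted p for Ifit2 and Ifih1 = 3.3e-15 and 3.9e-17). The chemokine genes Ccl4, Ccl12 and Cxcl10 were higher by 5.03 ± 0.25, 4.81 ± 0.36 and 4.46 ± 0.28 (adjusted p = 2.7e-16, 2.2e-12 and 6.4e-14), with another probe of Ccl4 at 3.73. Il12b and Il6 were higher by 3.67 ± 0.18 and 3.31 ± 0.34, and Tnf by 2.25 ± 0.36 (adjusted p = 1.8e-05). Falls were also strong, led by Tcf21, a transcription factor of splenic mesenchyme (-2.76 ± 0.28, adjusted p = 5.7e-09), and Slc40a1, the cellular iron exporter ferroportin (-2.65 ± 0.22, adjusted p = 4.8e-11). Id4, Gpd1 and Hpgd, an inhibitor of helix-loop-helix factors and enzymes of glycerol and prostaglandin metabolism, fell by 2.40 ± 0.29, 2.20 ± 0.24 and 2.11 ± 0.22 on the log2 scale.

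The 3 h comparison called 1520 genes, 1041 higher and 479 lower, 597 of them changed at least 2-fold. Of 44 interferon-stimulated genes 41 rose, 42 adjusted over the list alone, with a median of 2.09 (adjusted p = 1.9e-82, and adjusted p = 3.55e-14 with an estimated correlation). Interferon-gamma-induced GTPases and related genes rose in 17 of 22 cases, also 17 adjusted over the list alone, for example Gbp2 (3.44 ± 0.25) and Irgm1 (2.08 ± 0.18), which act against intracellular pathogens (adjusted p = 9.09e-07 with an estimated correlation). Of 9 measured interferon genes of type I and III only Ifnab passed (1.84 ± 0.24, adjusted p = 5.6e-07). NF-kB pathway genes rose in 16 of 20 cases, 18 adjusted over the list alone, and chemokines in 14 of 30 with 1 lower, 17 and 1 adjusted over the list alone (adjusted p = 8.27e-06 and 3.9e-07 with an estimated correlation). JAK-STAT and SOCS genes rose in 6 of 19 cases, 11 adjusted over the list alone, with Stat2 (2.03 ± 0.16) and Socs1 (2.11 ± 0.27) among them. MHC class I presentation genes rose in 7 of 16 cases, 11 adjusted over the list alone, with the peptide transporter Tap1 at 1.54 ± 0.26 (adjusted p = 0.0266 with an estimated correlation). Acute phase and antimicrobial genes rose in 7 of 18 cases, 9 adjusted over the list alone, with Serpina3n (2.89 ± 0.28) and Saa3 (1.97 ± 0.27). For immediate early genes, with 8 higher and 1 lower, the call of the list was lost (adjusted p = 0.099 with an estimated correlation). All probes tested gave 2373 called probes and array weights 2599 genes.

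At 9 h most interferon-stimulated genes were again raised. Ms4a6d, a membrane protein of macrophages, rose by 4.71 ± 0.22 on the log2 scale (adjusted p = 1.8e-16), Slfn4, a myeloid member of the Schlafen family, by 4.32 ± 0.35, and Il1r2, the decoy receptor for interleukin 1, by 3.66 ± 0.26. Gzmb, the granzyme of cytotoxic lymphocytes, was higher by 3.10 ± 0.31 (adjusted p = 3.6e-09) and Il10, an anti-inflammatory cytokine, by 1.83 ± 0.24. The macrophage mannose receptor gene Mrc1 fell by 2.33 ± 0.36 (adjusted p = 2.3e-05) and the eosinophil chemokine gene Ccl24 by 1.89 ± 0.19 (adjusted p = 7.1e-09). Clec9a, a receptor of cross-presenting dendritic cells, changed by -1.02 ± 0.25 (adjusted p = 0.0064).

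There were 1062 called genes at 9 h, 639 higher and 423 lower. Interferon-stimulated genes were higher in 38 of 44 cases, 41 adjusted over the list alone (median 1.77, adjusted p = 4.57e-15 with an estimated correlation). GTPases and related genes were higher in 18 of 22 cases, 18 with 1 lower adjusted over the list alone (adjusted p = 3.69e-07 with an estimated correlation), and acute phase genes in 7 of 18, 8 adjusted over the list alone (adjusted p = 1.29e-06 with an estimated correlation). In that list Lcn2 stood at 3.34 ± 0.37, Saa3 at 2.64 ± 0.27 and the complement factor gene Cfb at 1.68 ± 0.21. T cell markers moved downward, 4 of 17 lower and 7 adjusted over the list alone, with a median of -0.46 (adjusted p = 0.0338 with an estimated correlation). The T cell receptor chain gene Cd3g changed by -0.90 ± 0.18 and the co-stimulatory receptor Cd28 by -0.74 ± 0.18 (adjusted p = 0.0008 and 0.0084). Neutrophil markers were higher in 7 of 18 cases, 9 adjusted over the list alone, with Mmp8 at 3.33 ± 0.34 and S100a8 at 1.40 ± 0.27 (adjusted p = 0.0448 with an estimated correlation). Glycolysis genes were higher in 2 of 16 cases, 5 adjusted over the list alone (adjusted p = 0.0294 with an estimated correlation). The 2 were Hk2 (0.91 ± 0.18), which encodes an early enzyme of the pathway, and Pfkfb3 (0.98 ± 0.19). The count was 1605 with all probes tested, 1786 with array weights and 423 with a minimum of 2-fold.

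At 24 h Ms4a6d (4.03 ± 0.22), Ifit3 (3.27 ± 0.30) and Ifi44l (3.10 ± 0.31) remained among the strongest rises, and Cd5l, a survival factor secreted by macrophages, was higher by 2.98 ± 0.44 (adjusted p for Ms4a6d and Cd5l = 1.9e-14 and 1.6e-05). Ly6c1, a surface protein of monocytes and endothelium, rose by 2.15 ± 0.24 and Fcgr1, the high-affinity IgG receptor, by 1.15 ± 0.21 (adjusted p = 6.6e-08 and 0.00031). Slc25a37, the mitochondrial iron importer of erythroid cells, fell by 1.71 ± 0.34 and Fn3k, an enzyme abundant in red cells, by 1.72 ± 0.42 (adjusted p = 0.0011 and 0.0078). The lectin genes Reg2, Reg3g and Reg3a, which the pancreas and gut can express, were higher by 4.75 ± 1.39, 4.38 ± 1.14 and 3.76 ± 0.99 (adjusted p = 0.03, 0.015 and 0.014), with Reg2 and Reg3g measured on 3 of the 24 h arrays. Without replicate 3 of the 24 h arrays their adjusted p-values were 0.221, 0.146 and 0.12. The pancreas gene mean of the 24 h arrays ran from 0.30 to 5.30. Without CpG ODN the log2 ratio of Reg2 reached 4.27 on an untreated C57BL/6 control array and that of Reg3g 3.51 on an untreated TNF-KO array.

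**Figure D1:**
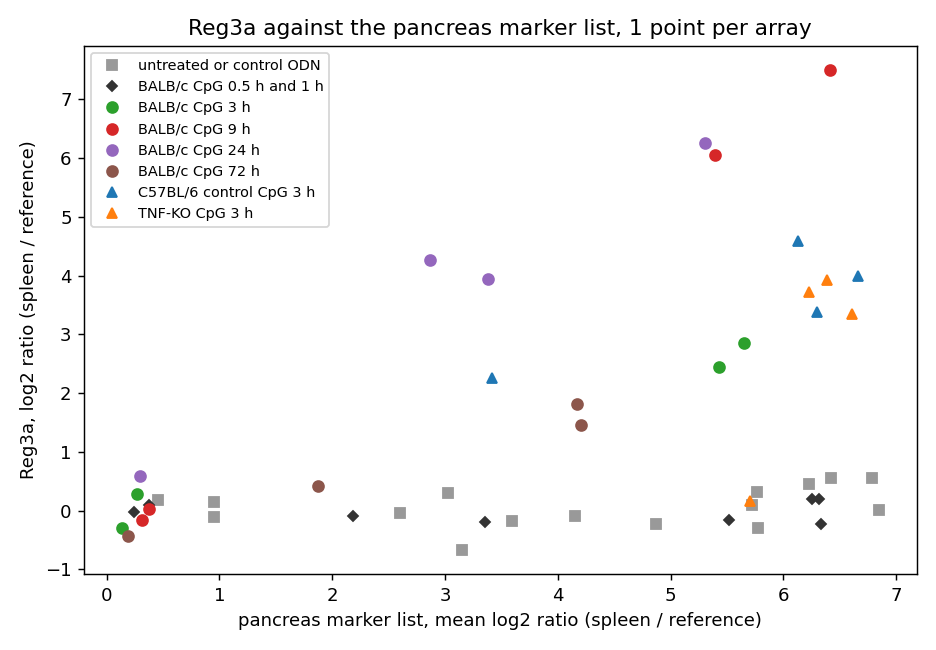
Log2 ratio (spleen over reference) of Reg3a against the mean log2 ratio of the pancreas genes, 1 point per array, coloured by group. Reg3a reached at most 0.562 over the untreated and control ODN arrays of BALB/c, whose pancreas mean reached 6.782, and averaged 3.764 at 24 h after CpG ODN.

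The 24 h comparison called 1290 genes, 1043 higher and 247 lower. Interferon-stimulated genes were higher in 33 of 44 cases and GTPases and related genes in 14 of 22. Adjusted over the list alone these were 37 and 16 (adjusted p = 5.81e-08 and 0.00061 with an estimated correlation). Markers of monocytes and macrophages were higher in 8 of 19 cases, 10 adjusted over the list alone, with a median of 0.82 (adjusted p = 0.0218 with an estimated correlation). MHC class I presentation genes were higher in 7 of 16 cases, 12 adjusted over the list alone, with the immunoproteasome genes Psmb9 (1.55 ± 0.24) and Psme1 (1.11 ± 0.16) among them. Erythroid genes were lower in 4 of 22 cases, 10 adjusted over the list alone, with a median of -0.76 (adjusted p = 2.9e-06, and adjusted p = 0.274 with an estimated correlation). Their mean per group was 3.87 in untreated spleen and 3.18 at 24 h. One probe of the anion exchanger gene Slc4a1 gave -1.61 ± 0.41 (adjusted p = 0.011, and 0.113 without replicate 3) and another -0.14. The count became 1998 with all probes tested, 1950 with array weights and 354 with a minimum of 2-fold. It was 605 without replicate 3 and 2194 without replicate 4 of the 24 h arrays.

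At 72 h Apol10a, an apolipoprotein L gene, rose by 4.33 ± 0.44 on the log2 scale, the guanylate-binding protein gene Gbp2b by 3.37 ± 0.26 and Cxcl9, a chemokine for activated T cells, by 2.59 ± 0.42 (adjusted p for Apol10a and Gbp2b = 4.1e-08 and 1e-10). Gzmb was higher by 2.60 ± 0.31 and the natural killer receptor genes Klrk1 and Klra3 by 1.33 ± 0.23 (other probes from 0.36 to 1.41) and 1.16 ± 0.17 (adjusted p for Gzmb and Klra3 = 5.3e-07 and 1.6e-05). Ctsg and Prtn3, serine proteases made by granulocyte precursors, rose by 2.09 ± 0.36 and 1.61 ± 0.35 (adjusted p = 0.00022 and 0.0031). Lower transcripts included Mmp12, a macrophage elastase (-1.49 ± 0.20, adjusted p = 7.7e-06), and Lef1, a transcription factor of naive T cells (-1.02 ± 0.19, adjusted p = 0.00071). Ighd, the heavy chain of IgD on naive B cells, measured on 3 of the 72 h arrays, was at -2.42 ± 0.62 (adjusted p = 0.013), and at -0.75 without replicate 3 of the 72 h arrays (adjusted p = 0.21).

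Among all genes 1616 passed at 72 h, 982 higher and 634 lower. Of 22 GTPases and related genes 15 were higher, 18 adjusted over the list alone, with a median of 1.34, and of 44 interferon-stimulated genes 30, 34 adjusted over the list alone, with a median of 0.93 (adjusted p = 5.55e-05 for both with an estimated correlation). MHC class I presentation genes were higher in 8 of 16 cases, 11 adjusted over the list alone (adjusted p = 0.0431 with an estimated correlation). Natural killer and cytotoxic genes were higher in 8 of 15 cases, 11 adjusted over the list alone (adjusted p = 0.0968 with an estimated correlation). T cell markers were lower in 7 of 17 cases, 10 adjusted over the list alone, such as Cd28 (-1.07 ± 0.18) and Cd3e (-0.94 ± 0.16) (adjusted p = 0.0595 with an estimated correlation). Cell cycle genes were higher in 4 of 32 cases, 17 adjusted over the list alone, with a median of 0.75 (adjusted p = 0.387 with an estimated correlation). Erythroid genes were higher in 5 of 22 cases beside them, 7 adjusted over the list alone, among them the erythroid transcription factor Gata1 at 0.91 ± 0.20, and the mean of the list was 4.50 against 3.87 in untreated spleen (adjusted p = 0.387 with an estimated correlation). The count was 2659 with all probes, 5667 with array weights and 331 with a minimum of 2-fold. It was 1061 without untreated replicate 5, and 931, 724, 679 and 2540 without replicates 1 to 4 of the 72 h arrays.

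Over the 6 times 1089 genes changed by at least 2-fold at 1 time or more. Each was assigned to the time of its largest change in either direction, whether or not the change at that time passed. Of the rises 4 were largest at 0.5 h, 149 at 1 h, 393 at 3 h, 91 at 9 h, 96 at 24 h and 107 at 72 h. Of the falls 1, 4, 67, 70, 47 and 60 were largest at these times. Fos was higher by 4.10 ± 0.27 at 1 h, Cxcl2 by 5.32 ± 0.32 at 1 h, Ifit2 by 4.57 ± 0.26 at 3 h and 3.99 ± 0.26 at 9 h, Ms4a6d by 4.71 ± 0.22 at 9 h, and Gbp2b by 3.37 ± 0.26 at 72 h.

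**Figure D2:**
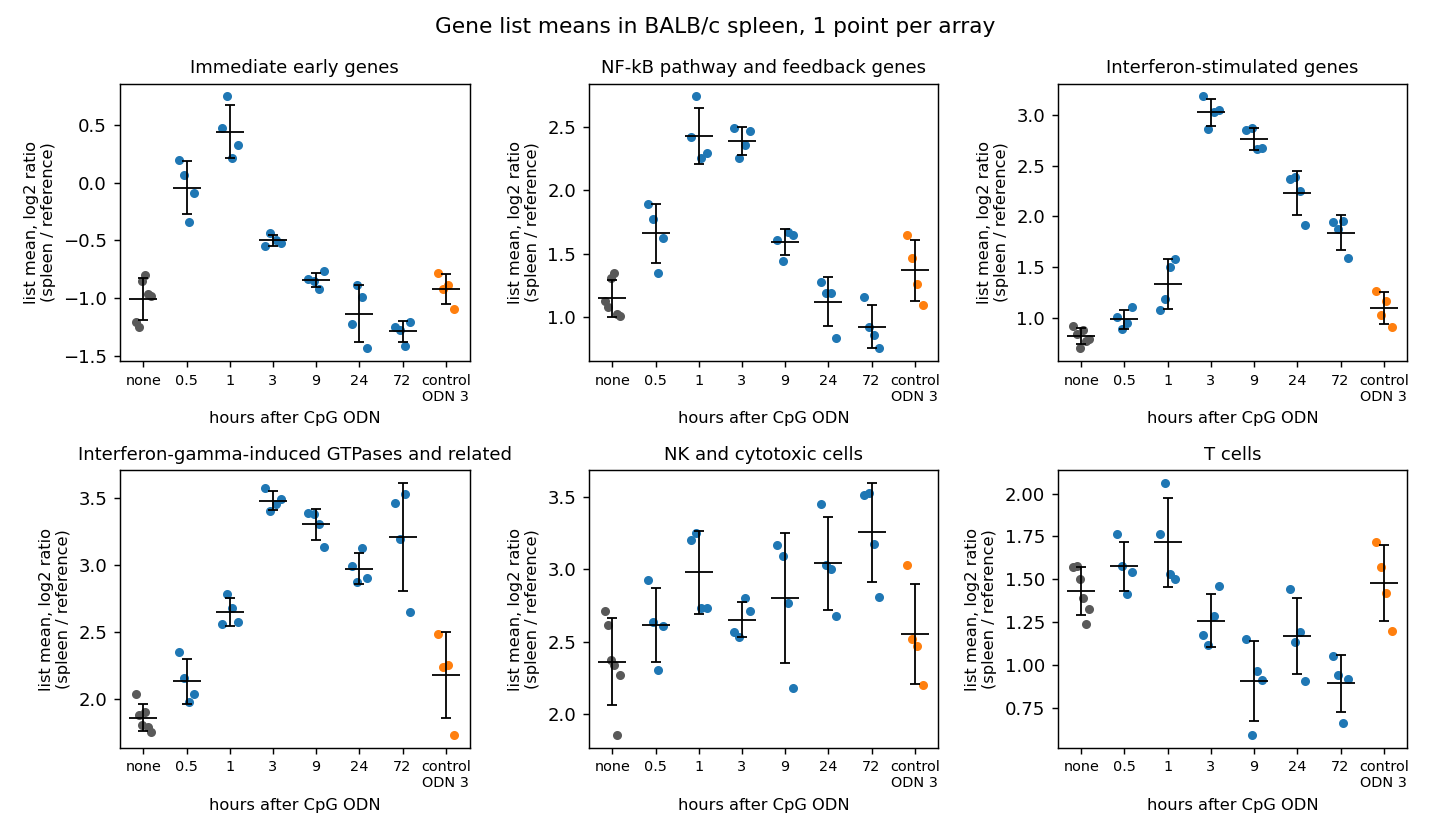
Mean log2 ratio (spleen over reference) of 6 gene lists in BALB/c spleen, 1 point per array, with the group mean and SD as bars, against hours after CpG ODN and after control ODN at 3 h. Immediate early and NF-kB genes stand highest at 1 h, interferon-stimulated genes at 3 h, and T cell markers lowest at 9 and 72 h.

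**Figure D3:**
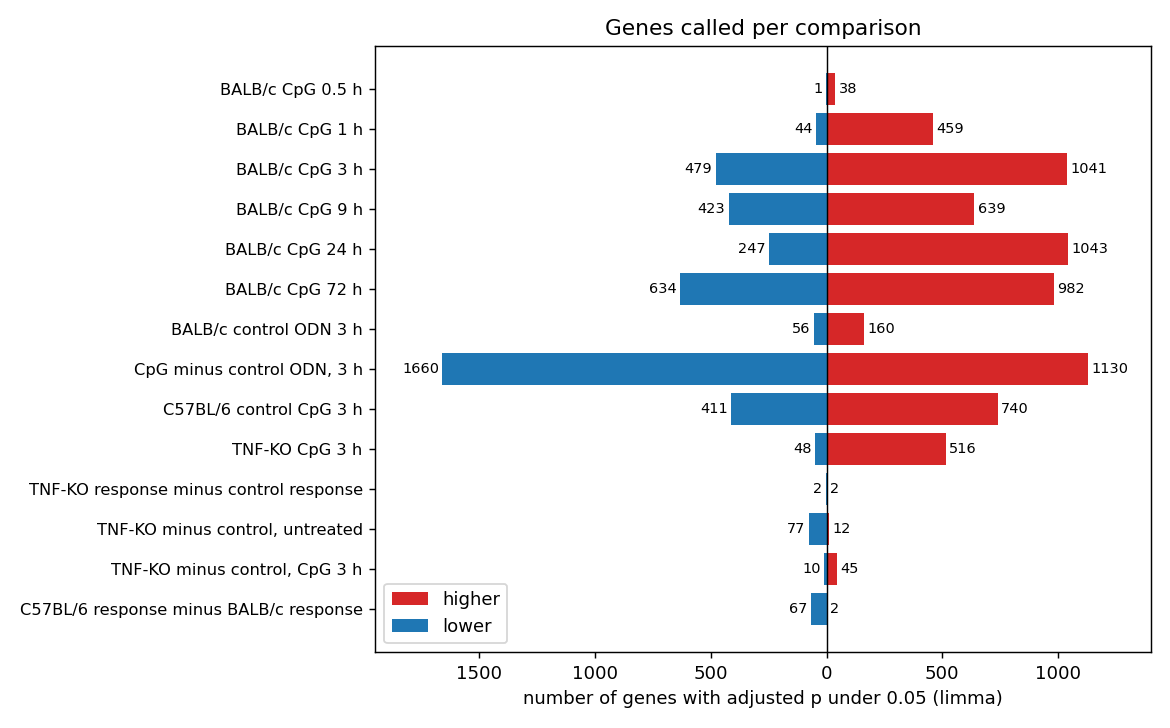
Number of genes with an adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0. The CpG groups of BALB/c run from 39 genes at 0.5 h to 1616 at 72 h, and the difference between the responses of TNF-KO and control mice holds 4.

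The control ODN mixture tested what the same dose of closely related ODN did without the exchanged CG motifs. CpG ODN 1555 and control ODN 1612 are 15 bases long and differ by C7T, and CpG ODN 1466 and control ODN 1471 are 10 bases long and differ by C5G and G6C, with positions counted from 1 at the 5' end. The CG dinucleotides number 2 in 1555, 1 in 1466, 1 in 1612 and 0 in 1471. At 3 h after control ODN, Mmp8 was higher by 2.08 ± 0.34 on the log2 scale, S100a9, a calcium-binding protein of neutrophils, by 1.86 ± 0.43, and Hp, the acute phase protein haptoglobin, by 1.80 ± 0.29 (adjusted p = 0.0061, 0.032 and 0.0061). Another probe of Hp gave 0.04. Myd88, the adaptor of most Toll-like receptors, was higher by 1.01 ± 0.21 (adjusted p = 0.024). Ccl4 (0.40 ± 0.25), Cxcl10 (0.38 ± 0.29), Ifit2 (0.45 ± 0.26), Il12b (-0.36 ± 0.23) and Tnf (0.23 ± 0.36), which were chosen after their values were seen, did not pass (adjusted p = 0.355, 0.439, 0.307, 0.368 and 0.733).

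After control ODN 216 genes passed, 160 higher and 56 lower, and 3412 had an unadjusted p under 0.05. Neutrophil markers were higher in 3 of 18 cases, 10 adjusted over the list alone, with a median of 0.76 (adjusted p = 3.08e-06, and adjusted p = 0.324 with an estimated correlation). Monocyte and macrophage markers were higher in 1 of 19 cases, 11 adjusted over the list alone, and MHC class II genes in 1 of 11, 7 adjusted over the list alone (adjusted p = 0.315 and 0.324 with an estimated correlation). Interferon-stimulated genes were higher in 3 of 44 cases, 4 with 1 lower adjusted over the list alone (adjusted p = 0.682 with an estimated correlation). None of the 8 lists called with the preset correlation kept its call, and none of the 19 called genes named by rule passed without each array in turn, the adjusted p of Mmp8 reaching 0.156 without control ODN replicate 1. With arrays scaled to the same spread limma called 0 genes, with 2707 at an unadjusted p under 0.05, and the count was 38 with only the groups compared, 134 with array runs as a random block, 63 with a minimum of 2-fold and 1425 with array weights. It was 0, 8, 3 and 2115 without control ODN replicates 1 to 4, and 37, 12, 33 and 3 without untreated replicates 1, 2, 5 and 6. Leaving out arrays of other groups, which share the estimate of spread, gave 142 without replicate 3 at 1 h, 137 without replicate 3 at 3 h, 424 and 388 without replicates 2 and 4 at 24 h, and 123 without replicate 2 at 72 h.

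Set directly against control ODN at the same dose and time but in other array runs, spleens after CpG ODN had far higher chemokine, interferon-stimulated and cytokine mRNAs. Ccl4 was higher by 4.64 ± 0.28 on the log2 scale (95% interval 4.08 to 5.20), Ifit2 by 4.12 ± 0.28, Cxcl10 by 4.08 ± 0.31 and Il12b, measured on 2 of the control ODN arrays, by 4.02 ± 0.24 (adjusted p for Ifit2 and Il12b = 7.9e-13 and 8.2e-13). Il6 was higher by 3.18 ± 0.37, Cd14 by 2.29 ± 0.31 and Tnf by 2.02 ± 0.39, with a 95% interval of 1.23 to 2.81 (adjusted p = 1.1e-07, 2.3e-06 and 0.00037). Lower after CpG ODN were Tcf21 (-3.21 ± 0.31), Slc40a1 (-3.08 ± 0.24) and Xcr1, a chemokine receptor of cross-presenting dendritic cells (-1.18 ± 0.22) (adjusted p = 2.5e-09, 2e-11 and 0.00032). Of the genes raised after control ODN, Mmp8 and Slfn4 were higher still after CpG ODN, by 1.07 (95% interval 0.31 to 1.83, adjusted p = 0.0434) and 2.25 (1.47 to 3.02, adjusted p = 6.4e-05), as was Cd14. The difference of Mmp8 was lost without any of CpG replicates 1, 3 and 4 or control ODN replicates 3 and 4, being 0.63 without the last (adjusted p = 0.207), and with array weights, all probes tested or only the groups compared (adjusted p = 0.0651, 0.0522 and 0.11). For others no difference between the mixtures passed. The difference of CpG minus control ODN was 0.01 for Lrg1, a leucine-rich glycoprotein of neutrophils (95% interval -0.69 to 0.71, adjusted p = 0.987), -0.14 for Hp (-0.80 to 0.51, adjusted p = 0.807), -0.49 for S100a9 (-1.45 to 0.48, adjusted p = 0.521), 0.41 for Myd88 (-0.05 to 0.88, adjusted p = 0.212) and -0.54 for Cxcr2, a chemokine receptor of neutrophils (-1.0 to -0.09, adjusted p = 0.0881). With arrays scaled to the same spread it was 0.39 for Hp, 0.74 for S100a9 and 0.69 for Myd88, of which Myd88 passed (adjusted p = 0.486, 0.414 and 0.0274). The sign for Lrg1 and Hp also turned with single arrays left out, to -0.36 for Lrg1 without control ODN replicate 4 and to 0.13 for Hp without control ODN replicate 2. The other probe of Hp rose by 0.64 after CpG ODN, where the probe used rose by 1.66. It hardly changed after control ODN, so by that probe the difference for Hp was positive.

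The arrays of the mixtures differed in 2790 genes, 1130 higher and 1660 lower after CpG ODN. They shared no array run, so mixture and run cannot be told apart in this count. Interferon-stimulated genes were higher in 38 of 44 cases and GTPases and related genes in 16 of 22. Adjusted over the list alone these were 39 and 16, with 1 gene of the latter list lower (adjusted p = 1.06e-09 and 0.000286 with an estimated correlation). NF-kB pathway genes were higher in 12 of 20 cases, 13 adjusted over the list alone, and inflammatory cytokines in 9 of 26, 10 adjusted over the list alone (adjusted p = 0.00148 and 1.21e-05 with an estimated correlation). Chemokines were higher in 14 and lower in 3 of 30 cases, 16 and 4 adjusted over the list alone (adjusted p = 0.000111 with an estimated correlation). MHC class II genes were lower in 5 of 11 cases, 7 adjusted over the list alone, and dendritic cell markers in 4 of 11, 5 adjusted over the list alone (adjusted p = 0.206 and 0.257 with an estimated correlation). The count was 4403 with all probes tested and 878 with a minimum of 2-fold. It was 1850 and 1625 without control ODN replicates 1 and 3.

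In C57BL/6 control mice Tnf stood at 0.78, 0.62, 0.78 and 0.58 on the log2 ratio scale in untreated replicates 1 to 4 and at 4.30, 3.61, 4.59 and 3.16 after CpG ODN. In TNF-KO mice it stood at -0.61, -0.09, -0.29 and 0.09 in untreated replicates 1 to 4 and at 0.43, -0.34, -0.44 and -0.30 after CpG ODN. The group means were 0.69 ± 0.105 and 3.92 ± 0.652 in controls and -0.22 ± 0.299 and -0.16 ± 0.402 in TNF-KO (SD, n = 4 each).

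In C57BL/6 control spleen 3 h after CpG ODN, chemokine genes were among the largest rises. Ccl4 was higher by 4.60 ± 0.23 on the log2 scale, with another probe at 2.39, Slfn4 by 4.33 ± 0.37 and Cxcl10 by 3.61 ± 0.24 (adjusted p = 9.1e-10, 6.7e-07 and 3.7e-08). Tnf was higher by 3.23 ± 0.27 (adjusted p = 6.4e-07), Nfkbiz by 2.95 ± 0.18 (adjusted p = 1.2e-08) and Mt2, a metal-binding metallothionein, by 3.41 ± 0.43. Falls included Slc40a1 (-2.77 ± 0.38, adjusted p = 0.00012), Tmem273 (-2.55 ± 0.22, adjusted p = 7.7e-07), Acot1, an acyl-CoA thioesterase (-2.39 ± 0.23, adjusted p = 3.4e-06), Olfml1 (-2.35 ± 0.25, adjusted p = 7e-06) and Tcf21 (-2.26 ± 0.35, adjusted p = 0.00037).

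A total of 1151 genes passed in C57BL/6 controls, 740 higher and 411 lower. Interferon-stimulated genes rose in 36 of 44 cases, 38 adjusted over the list alone (median 1.66, adjusted p = 1.82e-05 with an estimated correlation), with Ifi204 at 2.88 ± 0.17 and Eif2ak2 at 2.24 ± 0.16. Chemokines rose in 16 of 29 cases, 17 with 2 lower adjusted over the list alone, and NF-kB pathway genes in 14 of 20, 15 adjusted over the list alone (adjusted p = 0.000555 and 0.0023 with an estimated correlation). Neutrophil markers were higher in 8 of 18 cases, 9 adjusted over the list alone, with Mmp8 at 3.87 ± 0.41 and the receptor Csf3r at 1.48 ± 0.19, other probes from 0.65 to 1.10 (adjusted p = 0.0384 with an estimated correlation). None of 13 pancreas genes passed, while their median was 1.76 (adjusted p = 0.00535, and adjusted p = 0.477 with an estimated correlation). Of 14903 genes tested in both strains, 492 were higher in both, where independent lists of 1029 in BALB/c and 737 in C57BL/6 would share 50.9, and 162 were lower in both, where lists of 477 and 411 would share 13.2. No gene was called in opposite directions, and these comparisons share no arrays. The count was 1735 with all probes tested and 512 with a minimum of 2-fold, and 765 without replicate 2 of the CpG arrays.

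In TNF-KO spleen CpG ODN still raised chemokine, interferon-stimulated and neutrophil transcripts at 3 h. Ccl4 rose by 5.49 ± 0.23 on the log2 scale, with another probe at 3.46, Slfn4 by 5.25 ± 0.37, Ifi204 by 3.66 ± 0.17 and Cxcl10 by 3.82 ± 0.24 (adjusted p = 4.1e-11, 5.1e-08, 1.2e-10 and 1.2e-08). The cytokine genes Il1b, Il6 and Il12b rose by 2.57 ± 0.28, 2.23 ± 0.35 and 2.62 ± 0.42, with Il12b measured on 2 of the untreated TNF-KO arrays. Tmem273 (-2.04 ± 0.22, adjusted p = 9.2e-06), Slc45a3 (-1.78 ± 0.26, adjusted p = 0.00032) and Acot1 (-1.33 ± 0.23, adjusted p = 0.0015) fell.

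There were 564 called genes in TNF-KO, 516 higher and 48 lower. Interferon-stimulated genes rose in 38 of 44 cases and GTPases and related genes in 13 of 22. Adjusted over the list alone these were 41 and 18 (adjusted p = 9.41e-09 and 2.44e-05 with an estimated correlation). NF-kB pathway genes rose in 11 of 20 cases, 15 adjusted over the list alone, with Nfkbiz at 3.23 ± 0.18 and Tnfaip3 at 1.54 ± 0.22 (adjusted p = 0.00142 with an estimated correlation). Neutrophil markers were higher in 9 of 18 cases, 10 adjusted over the list alone, with Mmp8 at 4.10 ± 0.44 on 3 of the TNF-KO CpG arrays, another probe at 3.02 (adjusted p = 0.00958 with an estimated correlation). Chemokines rose in 10 of 29 cases, 12 adjusted over the list alone (adjusted p = 0.000177 with an estimated correlation). Of 14951 genes, 361 were higher in both genotypes, against 25.5 for independent lists of 740 and 516, and 27 were lower in both, against 1.3 for lists of 411 and 48. Of the 411 genes lower in controls 79.8% had the same sign in TNF-KO, and of the 740 higher in controls 94.9% did. The count was 357 with a minimum of 2-fold and 353 without replicate 1 of the TNF-KO CpG arrays.

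The direct test of whether the responses of both genotypes differed called 4 genes with limma. Tnf responded less in TNF-KO, by -3.17 ± 0.38 on the log2 scale (adjusted p = 0.0018), and Stip1, a co-chaperone, by -1.42 ± 0.24 (adjusted p = 0.042). Olfml1, an olfactomedin-like gene that fell in controls, had a response higher by 2.49 ± 0.35 in TNF-KO, and Kazald1 by 1.74 ± 0.28 (adjusted p = 0.0098 and 0.035). Tnf and Olfml1 passed without each array in turn, while Stip1 and Kazald1 reached adjusted p-values of 0.156 and 0.132. At an unadjusted p under 0.05 there were 1199 genes, and in simulated data the test recovered 27 of 100 genes changed by 1 on the log2 scale and 94 of 100 changed by 2. Of the lists, erythroid genes had a median difference of 1.19, monocyte markers of 0.29 and interferon-stimulated genes of 0.30 (adjusted p = 0.752, 0.492 and 0.764 with an estimated correlation). With arrays scaled to the same spread the split of 2 higher and 2 lower became 2 higher and 1 lower. The count was 2 with all probes tested, 2 with array runs as a block and 7 with array weights. It was 2 without any of control untreated replicates 1 to 4, control CpG replicate 1, TNF-KO untreated replicates 2 and 3 or TNF-KO CpG replicates 1 to 3, and 8 without control CpG replicate 4.

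Genes fixed by their 3 h change in BALB/c gave a summary of both directions of the response. The mean of 505 induced genes rose by 1.19 on the log2 scale in controls and by 1.24 in TNF-KO, a difference of 0.05 ± 0.161 (SE, two-sided exact permutation p = 0.831). The mean of 84 repressed genes changed by -1.23 in controls and by -0.48 in TNF-KO, a difference of 0.75 ± 0.189 (two-sided exact permutation p = 0.0135, smallest possible p 0.00041). With no fold minimum on the choice of genes the repressed difference was 0.34 and no longer passed.

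**Figure D4:**
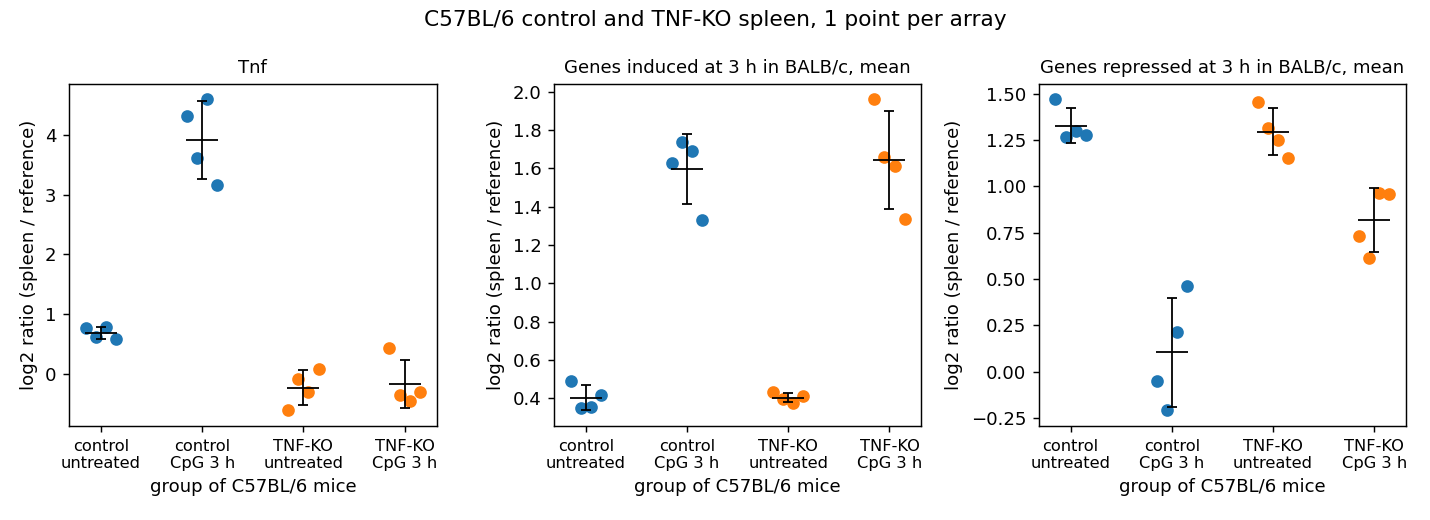
Log2 ratio (spleen over reference) of Tnf, and the mean log2 ratio of genes induced and of genes repressed at 3 h in BALB/c, in the 4 groups of C57BL/6 mice, 1 point per array with mean and SD. Induced genes average 1.597 in controls and 1.642 in TNF-KO after CpG ODN, and repressed genes 0.104 and 0.818.

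Untreated TNF-KO spleen had lower levels of red cell transcripts than untreated control spleen. The difference was -2.31 ± 0.45 for Fech, the last enzyme of heme synthesis, -2.58 ± 0.53 for Kel, a blood group protein, -3.22 ± 0.65 for Ctse, cathepsin E, and -2.51 ± 0.39 for Sncg, gamma-synuclein (adjusted p for Sncg = 0.0087). It was -3.02 ± 0.50 and -1.66 ± 0.25 for the interferon-stimulated genes Rsad2 and Isg15 (adjusted p = 0.013 and 0.0087). Higher in TNF-KO were Irs3, an insulin receptor substrate (2.97 ± 0.28, adjusted p = 6.5e-05), and Paip1, a regulator of translation (1.63 ± 0.20, adjusted p = 0.0016). Tnf itself differed by -0.91 ± 0.27 (adjusted p = 0.15).

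The comparison of untreated mice called 89 genes, 12 higher and 77 lower. Erythroid genes were lower in 6 of 22 cases, 18 with 1 higher adjusted over the list alone, with a median of -2.33 (adjusted p = 4.73e-19, and adjusted p = 0.0467 with an estimated correlation). Their mean was 1.92, 1.74, 1.82 and 3.84 in untreated TNF-KO replicates 1 to 4, and 4.19 ± 0.53 (SD, n = 4) in untreated controls. Cell cycle genes had a median of -0.62 with none called, 7 lower adjusted over the list alone, and their mean was -1.52, -1.53, -1.42 and -0.21 in the TNF-KO replicates (adjusted p = 0.348 with an estimated correlation). Interferon-stimulated genes were lower in 4 of 44 cases, 5 adjusted over the list alone, and pancreas genes had a median of 1.74 (adjusted p = 0.534 and 0.631 with an estimated correlation). Of 18 called genes named by rule, Irs3 and Paip1 passed without each array in turn. With arrays scaled to the same spread 23 genes passed, 6 higher and 17 lower, a share of 26.1% higher in place of 13.5%. The count was 10 with only the groups compared, 188 with array weights, 22 with the pancreas mean as a covariate and 343 with array runs as a block. It was 8, 10, 2 and 379 without untreated TNF-KO replicates 1 to 4, 10, 11 and 25 without untreated control replicates 1, 2 and 4, 57 and 24 without TNF-KO CpG replicates 1 and 2, and 47 without control CpG replicate 3.

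After CpG ODN the levels in TNF-KO and control spleen differed in 55 genes, 45 higher and 10 lower in TNF-KO. The difference was -4.08 ± 0.27 for Tnf (adjusted p = 1.3e-07). The chemokine receptor genes Ccr2 and Ccr1, carried by monocytes, were higher by 2.14 ± 0.25 and 1.80 ± 0.18 (adjusted p = 0.00034 and 0.00014). Id4, Tcf21 and Olfml1 were higher by 2.35 ± 0.37, 2.18 ± 0.35 and 1.73 ± 0.25 (adjusted p = 0.0061, 0.0063 and 0.0024), and Irs3 by 2.20 ± 0.28, while Tcf21 had an adjusted p of 0.0525 with arrays scaled to the same spread. Monocyte and macrophage markers were higher in 2 of 19 cases, 4 adjusted over the list alone (adjusted p = 0.263 with an estimated correlation). Cell cycle and erythroid genes had medians of -0.69 and -1.07 (adjusted p = 0.398 and 0.427 with an estimated correlation). Of 15 called genes named by rule, 8 passed without each array in turn. The count was 22 with only the groups compared and 155 with array weights. It was 31 and 27 without TNF-KO CpG replicates 1 and 3, and 20, 19, 28 and 101 without control CpG replicates 1 to 4.

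The 3 h responses of C57BL/6 control and BALB/c mice differed in 69 genes. For 67 of them the change in C57BL/6 lay below that in BALB/c, which a smaller rise or a larger fall can give. Gbp2b and Ifi202b, which are interferon-inducible, differed by -3.71 ± 0.36 and -3.67 ± 0.34 on the log2 scale (adjusted p = 8.4e-10 and 4.2e-10), Cxcl11, a chemokine for activated T cells, by -3.03 ± 0.54 (adjusted p = 0.0011) and Ifit2 by -1.92 ± 0.41 (adjusted p = 0.0088). Ncoa1, a nuclear receptor coactivator, gave -4.16 ± 0.29 (adjusted p = 4e-14) with its probe of record and -0.52 with another. The higher responses in C57BL/6 were those of Clec5a, a myeloid lectin (1.30 ± 0.26, adjusted p = 0.0032, another probe 0.16), and Eva1a (1.36 ± 0.33, adjusted p = 0.046, and 0.159 without untreated control replicate 1). Interferon-stimulated genes responded less in 2 of 44 cases, 9 adjusted over the list alone, with a median of -0.45 (adjusted p = 1.14e-10, and adjusted p = 0.224 with an estimated correlation). Pancreas genes had a median of 2.65 and neutrophil markers of 0.51 (adjusted p = 0.519 for both with an estimated correlation). Array weights gave 110 genes, and no array run held both strains, so strain and array run cannot be told apart.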

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

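The tests of explanations and of other splits of the arrays in this part were chosen after the results were seen, as were the per-array measures searched for arrays that stand apart, while the differences of responses and of the repressed-gene mean were planned.

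Of 102 combinations of a group and a per-array measure searched for an array far from the others, 7 held one. Chance gives about 1 in 20, so 7 is little above that rate, and the measures share the same arrays. The pancreas mean of BALB/c 0.5 h replicate 4 was 0.375 and that of C57BL/6 control CpG replicate 2 was 3.413, both below the rest of their groups. The erythroid mean of BALB/c 3 h replicate 1 was 4.223, apart from its group. Tnf in TNF-KO CpG replicate 1 was 0.428, above the others of that group. The mean of the repressed genes in untreated C57BL/6 control replicate 1 was 1.471, above the other untreated controls. The remaining 2, in erythroid genes and in Reg3a, belong to patterns weighed here.

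The difference between the responses of TNF-KO and control mice held 4 genes, Tnf among them, which is the planned test of the interaction. Tnf, the deleted gene, is bound to be called in the real split of the genotypes and was therefore left out of the count of other splits. Without it 1 gene, Olfml1, passed, while Stip1 and Kazald1 no longer did. With the standing difference between the genotypes removed from each gene, 2 of 100 splits gave as many, the real one among them. None gave more. A count of 1 gene that another split also reached cannot exclude chance, for Olfml1 or for Stip1 and Kazald1. The mean of the repressed genes fell less in TNF-KO, with a difference of 0.747 between the genotypes' changes on the log2 scale, and no biological explanation was tested.

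Probes with no symbol or several, which only the alternative with all probes used, also responded. At 3 h in BALB/c 361 of 7093 such probes passed, 244 higher and 117 lower, out of 2373 called among all probes.

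Reg2, Reg3g and Reg3a were higher after CpG ODN in BALB/c, and within the 9 h and 24 h groups their levels were very uneven. Pancreatic tissue alone, with no effect of CpG ODN, is argued against for Reg3a, which was at most 0.562 over 10 untreated and control ODN arrays although their pancreas mean reached 6.782, against a mean of 3.764 and an SD of 2.349 at 24 h. Reg2 and Reg3g reached 4.273 and 3.507 without CpG ODN, on arrays with pancreas means of 6.421 and 5.766, so such tissue is a candidate source of part of their level. Their rise at 24 h was 4.751 and 4.377, and 4.653 and 4.338 with the pancreas mean as a covariate (limma, adjusted p = 9.24e-05 and 3.39e-05 with it). The covariate cannot decide whether such tissue was the whole cause, because neither gene was measured on 24 h replicate 4, whose pancreas mean was lowest (0.298). Neither rise passed without 24 h replicate 3. On 24 h replicates 1 to 3, with pancreas means of 2.866, 3.379 and 5.301, Reg2 stood at 3.855, 5.232 and 7.623. Untreated BALB/c replicate 3, with 5.717, had 2.894, the highest measured in its group. Pancreatic tissue carried with some spleens is a candidate source of the Reg3a transcripts, because Reg3a followed the pancreas mean within 3 time points (exact permutation p = 0.000506, 13824 permutations), while TNF-KO CpG replicate 4 was flat for it at 0.167 with a pancreas mean of 5.703. A response of pancreatic tissue to CpG ODN from 3 h on may account for Reg3a, as a hypothesis that was not tested. The 8 arrays of 0.5 h and 1 h reached at most 0.199, while TNF-KO CpG replicate 4 goes against such a response.

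Erythroid genes were lower in untreated TNF-KO spleen, except in replicate 4, whose erythroid mean of 3.837 stood apart from its group. A difference between array runs as the whole cause is argued against by the 3 runs that held untreated arrays of both genotypes. Within them, with 1 array against 1, the smallest fall was -1.946 and the largest -2.812, against an SD of 0.530 among untreated controls. Replicate 4 lay in another run, which held no untreated control. The TNF-KO and control CpG arrays of that run had erythroid means of 3.552 and 3.903, the highest of their groups. An effect of that run on replicate 4 is therefore not excluded. Replicate 4 as a mislabelled control array is argued against as well, since its Tnf level was 0.088 where untreated controls ran from 0.578 to 0.779, and its Irs3 level was 2.618 where no control exceeded 0.950. The genotype, and differences in age, blood content or housing between the colonies that the labels do not give, stay open and were not tested. Chance cannot be excluded for the 89 called genes, since 2 of 35 splits gave as many and the highest other split, which joined TNF-KO replicates 1 to 3 with control replicate 3, gave 322, while the count was 2 without TNF-KO replicate 3 and 379 without replicate 4.

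The responses of BALB/c and C57BL/6 controls differed in 69 genes, for 67 of which the change in C57BL/6 lay below that in BALB/c. Signal of single probes in BALB/c is a candidate explanation for part of them. Of 14 such genes that rose at least 2-fold in BALB/c and had other probes, 0 had other probes reaching 0.5 times the change. Among other risen genes it was 84 of 145 (two-sided Fisher exact p = 1.33e-05). The genes were chosen by the change of the probe used on these same arrays, which favours weaker other probes, and genes of the same arrays are not independent. A strain variant that weakens the probes in C57BL/6 would lower their level in untreated C57BL/6 as well. Only 38.8% of the genes, 26 of 67, had lower levels there, with a median difference of 0.162, so lower levels were not general. The difference was -4.482 for Ifi202b and -2.975 for Gbp2b but 0.839 for Ncoa1. For single genes such a variant cannot be told apart from a lower response, and levels of the strains cannot be told apart from array runs. A true difference between the strains stays open and was not tested apart from these, as does one between array runs, none of which held both strains. Chance is argued against for the count, though 100 splits cannot exclude it. With the standing difference between the strains removed from each gene only the real split, 1 of 100, gave as many. The highest other split gave 2. With that difference left in, 7 of 100 splits gave as many and the highest gave 2334. Leaving the difference in carries it into the responses, so those splits decide nothing.

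For the other counts except that for control ODN the real split gave more genes than the highest other split. It was 39 against 35 at 0.5 h, 503 against 380 at 1 h, 1520 against 634 at 3 h, 1062 against 262 at 9 h, 1290 against 724 at 24 h and 1616 against 463 at 72 h, the real split being the only 1 of 100 as large each time. It was 2790 against 695 for CpG against control ODN and 1151 against 1 in C57BL/6 controls. In TNF-KO it was 564 against 21, and for levels after CpG ODN 55 against 2, with 1 of 35 splits as large in each of these comparisons. Such shares are the smallest that 100 or 35 splits allow, and many counts were tested after the results were seen. Chance is therefore argued against for these counts but not excluded, least clearly at 0.5 h, where another split gave 35. For control ODN 3 of 100 splits gave 216 or more, the real one among them. The others gave 909 and 463 and joined control ODN replicates 1 to 3 with untreated replicate 3 or 1. They lie close to the real split and differ from it in replicate 4, without which the count was 2115. They thus show that replicate 4 was unlike its group, and a structure of the arrays beside the treatment was not tested.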

How the results depend on the processing

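The pancreas covariate was chosen after seeing the data, and all other alternatives were planned. Counts of 39 genes at 0.5 h, 503 at 1 h, 1520 at 3 h, 1062 at 9 h, 1290 at 24 h, 1616 at 72 h, 216 for control ODN, 2790 for CpG against control ODN, 1151 in C57BL/6 controls, 564 in TNF-KO, 4 for the interaction, 89 for untreated TNF-KO, 55 for levels after CpG ODN and 69 between strains stayed within 1.5 times under every alternative that is not named here, and the cause was not tested where a count moved. Scaling to the same spread gave 299 at 1 h, 0 for control ODN (2707 at an unadjusted p under 0.05 with limma) and 23 for untreated TNF-KO. All probes, which tests more features, gave 773 at 1 h, 2373 at 3 h, 1605 at 9 h, 1998 at 24 h, 2659 at 72 h, 4403 between the ODN mixtures, 1735 in C57BL/6 controls and 2 for the interaction. Only the groups compared, with fewer arrays behind the spread, gave 38 for control ODN, 10 for untreated TNF-KO and 22 for levels after CpG ODN. A minimum of 2-fold, which can only lower a count, gave 264, 597, 423, 354 and 331 from 1 h to 72 h, 63 for control ODN, 878 between the mixtures, 512 in C57BL/6 controls and 357 in TNF-KO. Array weights between 0.352 and 4.166 in BALB/c gave 85, 1001, 2599, 1786, 1950 and 5667 from 0.5 h to 72 h and 1425 for control ODN. Weights between 0.425 and 1.823 in C57BL/6 gave 7 for the interaction, 188 for untreated TNF-KO and 155 for levels after CpG ODN. Those between 0.364 and 4.416 over all arrays gave 110 between strains. The pancreas covariate gave 22 for untreated TNF-KO. Array runs as a random block gave 134 for control ODN (consensus correlation 0.008), the first run alone gave 1690 at 1 h and 29 at 0.5 h, and runs as a fixed block gave 2 for the interaction and 343 for untreated TNF-KO. Of 166 list calls 73 were made with an estimated correlation. The difference of the repressed-gene mean was 0.341 with no fold minimum on the genes and did not pass, where it had been 0.747.

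The replicate block gave 330 at 1 h, 989 at 72 h, 0 for control ODN (2697 at an unadjusted p under 0.05 with limma) and 158 for untreated TNF-KO. The labels name no shared animal or day for arrays with the same number, so the numbers were not taken to pair them. Some of them lay in the same array run, such as replicate 4 of control CpG, untreated TNF-KO and TNF-KO CpG, while other runs mixed numbers. A pairing is therefore not excluded. Their deviations from the group means correlated from -0.401 to 0.493 in BALB/c (mean 0.074, other numbers -0.021) and from -0.252 to 0.372 in C57BL/6 (mean 0.073, other numbers -0.023), and 16 of 32 and 10 of 16 arrays were closest on average to the arrays of their own number, where shuffled numbers gave means of 8.2 and 4.0 and as many in 21 and 17 of 1000 shuffles, a hint from the values that some share more.

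With each array left out in turn the counts ran from 21 to 50 at 0.5 h (21 and 22 without replicates 1 and 2), from 287 to 558 at 1 h (287 without replicate 2), from 1213 to 1613 at 3 h, from 775 to 1155 at 9 h, from 605 to 2194 at 24 h (605 without replicate 3, 2194 without replicate 4) and from 679 to 2540 at 72 h (931, 724, 679 and 2540 without replicates 1 to 4, and 1061 without untreated replicate 5). For control ODN they ran from 0 to 2115 (0, 8, 3 and 2115 without its replicates 1 to 4, 37, 12, 33 and 3 without untreated replicates 1, 2, 5 and 6, 142 and 137 without replicate 3 at 1 h and at 3 h, 424 and 388 without replicates 2 and 4 at 24 h, and 123 without replicate 2 at 72 h), and between the mixtures from 1625 to 3544 (1850 and 1625 without control ODN replicates 1 and 3). In C57BL/6 controls they ran from 765 to 1347 (765 without CpG replicate 2), in TNF-KO from 353 to 696 (353 without CpG replicate 1), for the interaction from 2 to 8 (8 without control CpG replicate 4, and 2 without any of control untreated replicates 1 to 4, control CpG replicate 1, TNF-KO untreated replicates 2 and 3 or TNF-KO CpG replicates 1 to 3), and between strains from 48 to 76. For untreated TNF-KO they ran from 2 to 379 (8, 10, 2 and 379 without its replicates 1 to 4, 10, 11 and 25 without control replicates 1, 2 and 4, 57 and 24 without TNF-KO CpG replicates 1 and 2, and 47 without control CpG replicate 3), and for levels after CpG ODN from 19 to 101 (31 and 27 without TNF-KO CpG replicates 1 and 3, and 20, 19, 28 and 101 without control CpG replicates 1 to 4). The list calls ran from 157 to 177, the induced-gene difference from -0.061 to 0.147 and the repressed-gene difference from 0.643 to 0.866.

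Of the values of named genes under alternatives 8209 kept their direction and side of the threshold, 583 no longer passed, 5 newly passed and 12 changed sign, none of which had passed. Between the mixtures these were Hp (0.389) and S100a9 (0.745) with scaling, Lrg1 with array weights (-0.066) and without CpG replicates 1 and 3 (-0.100 and -0.121) and control ODN replicate 4 (-0.362), and Hp without CpG replicate 2 (0.039) and control ODN replicates 1 and 2 (0.025 and 0.129), with arrays left out running up to 0.184 for Lrg1 (without control ODN replicate 3) and down to -0.602 for Hp (without control ODN replicate 4). The others were of Tnf in the TNF-KO response, at -0.015 with array weights, -0.067 without untreated TNF-KO replicate 1 and -0.139 without TNF-KO CpG replicate 1, the values with each array left out running up to 0.164, without untreated TNF-KO replicate 4. The signal over background of single spots was not used here, so what it limits is unknown.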

Other observations

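Some receptor and regulator genes of the innate pathways also changed in BALB/c after CpG ODN. Of 25 Toll-like receptor and adaptor genes 3 rose at 1 h, 8 adjusted over the list alone (adjusted p = 0.00753 with an estimated correlation), namely Cd14 (3.65 ± 0.28), Tlr2, a receptor for bacterial lipopeptides (2.53 ± 0.28), and Myd88 (1.07 ± 0.21). At 3 h 9 of them rose and 1 fell, with Tlr7, an endosomal sensor of RNA, at 1.49 ± 0.23 (adjusted p = 1.23e-05), and the call of the list was lost (adjusted p = 0.0551 with an estimated correlation). Of 8 interferon regulatory factors 5 rose at 3 h, including Irf9 at 1.06 ± 0.17, with another probe at 0.50, and Irf2 at 0.68 ± 0.17 (adjusted p = 0.0607 with an estimated correlation).

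Ligands of the TNF superfamily and their receptors also changed. At 1 h 4 of 28 rose, 6 adjusted over the list alone, with Fasl, the death ligand of cytotoxic lymphocytes, at 1.52 ± 0.23 (adjusted p = 4.74e-05) and Tnfsf14, a ligand of lymphotoxin pathways, at 1.06 ± 0.27, with another probe at -0.50, beside Tnf (adjusted p = 0.0197 for the list with an estimated correlation). At 3 h Fas, the receptor of Fasl, was higher by 1.89 ± 0.22 (adjusted p = 4.99e-08), while Tnfrsf17, a survival receptor of plasma cells, stood at -0.80 ± 0.23 (adjusted p = 0.0187), and the list as a whole did not pass (adjusted p = 0.0593). In C57BL/6 controls the glycolysis genes Pfkfb3, Hif1a, a transcription factor that induces them, and Hk2 were higher by 1.24 ± 0.22, 0.93 ± 0.19 and 1.00 ± 0.23 at 3 h, 3 of 16 and 5 adjusted over the list alone (adjusted p = 0.0143 with an estimated correlation).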
